A study of Mus musculus with 6 samples.

How the data were processed

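RNA was measured in CD8 T cells taken from the spleens of young and aged female C57BL/6 mice, stimulated through the T cell receptor and grown in interleukin 2, a T cell growth factor. Libraries were prepared with the QuantSeq kit, which reads a short stretch at the 3' end of each polyadenylated transcript, per the labels' protocols. A gene's value therefore counts transcript ends and does not grow with gene length. The genome build was GRCm38, also called mm10, per the submitters' processing notes. The aligner, the counting program, its treatment of strand and of reads with several matches, and the gene annotation are not given in the sources used here.

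The authors deposited 1 file per library with a value for each of 25655 Ensembl gene identifiers. The deposited values are CPM, reads scaled so that each column sums to 1000000, and 100% of the values are whole multiples of the smallest step within 0.001 reads. What 1 read is worth was therefore read off each file, and whole reads were recovered from it. The identifier ENSMUSG00000002633 has a blank value in every file and was left out. Symbols were found for 25600 identifiers in a table of gene names, and 55 had none. There were 12037 identifiers at 0 in all 6 libraries. Among them were all 475 listed antigen receptor genes, T cell receptor and immunoglobulin constant regions included, so nothing is said of these. The file of Aged replicate 2 names its value column as replicate 3. It was taken as replicate 2, following the record that ties files to samples, and its values differ from those of Aged replicate 3.

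Recovered totals ran from 1952552 reads in Aged replicate 1 to 2785915 in Young replicate 2, so that 1 read was worth 0.359 to 0.512 CPM. A count of 0 in a library allows up to 3 reads, or 1.08 to 1.54 CPM. Over the 3 libraries of a group this floor is 0.39 CPM in young and 0.449 CPM in aged cells. No molecular identifiers are described, and PCR reads without them are not independent molecules, so these floors cover counting error only. Replicates were compared by a chi-square test of their reads over genes with at least 10 reads. The statistic per degree of freedom was 1.72 to 2.9 over the 6 pairs within groups, a spread above counting noise alone. PCR duplicates or repeats of the same culture could give such a spread too, so it does not show what a replicate was.

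Groups and replicate numbers came from the sample titles. The tests, the gene lists and the rule for named genes were fixed before the data were examined. An edgeR test on counts had been planned, with limma on log2 values as the choice if the files held normalized values. Since they held CPM, the main test was limma with an intensity trend (limma 3.58.1, R 4.3.3) on log2(CPM + 1), two-sided, on genes with a mean of at least 1 CPM over the 6 libraries, with age group as the sole term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes in the log2 scale are aged minus young on log2(CPM + 1), which understates the change of genes at low levels. Folds given without the log2 scale are ratios of group means in CPM. The pseudocount and filter were varied among the alternatives.

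There were 54 gene lists of T cell states, pathways and other cell types, and 50 of them had at least 3 tested genes. They were tested with camera, which asks whether a list's genes moved more than other genes, at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over the lists. Beside it stand the number of members past the threshold over all genes, the number past it when adjusted over the list alone, and fry, which asks whether a list's genes moved on balance in one direction. With the correlation estimated from the data for each list, camera called 0 lists. In that setting 16 lists had an unadjusted p under 0.05, and the lowest adjusted p was 0.0625.

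Named genes were taken by 3 rules. The first took up to 12 genes per direction with the largest log2 fold change among called genes with a mean log2 value of at least 3 and groups that did not overlap, leaving out antigen receptor segments and gene models without a given name. The second took up to 4 members with the smallest p from every list called by camera and from a fixed set of further lists. The third took CD8, CD4 and CD3 genes and the most abundant member of every list of another cell type. This gave 154 genes, some of which are not reported here. Any other gene named in the text was chosen after its values were seen, or is given as an example of its list.

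Alternatives were DESeq2-type (RLE) and upper-quartile scaling, no filter and a stricter one, pseudocounts of 0.1 and 5, DESeq2 1.42.0 and limma-voom on the recovered reads, the replicate number as a block, thinning of every library to 1952552 reads, the estimated correlation, and leaving out each library in turn. The scalings had been planned for an edgeR fit and were applied to the CPM values in the limma fit. An edgeR 4.0.16 quasi-likelihood test on the recovered reads with TMM scaling, TMM-scaled CPM in the limma fit, and a run without genes whose exons overlap those of another gene were added after seeing the data. The edgeR test called 1464 genes higher and 1578 lower in aged cells.

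Gene positions and exon overlaps came from the GENCODE M21 annotation of GRCm38. Near-identical copies were searched with blastn 2.17.0, taking the last 200 bases of a gene's transcripts and counting matches in other genes of at least 95% identity over 100 bases. Of the 154 named genes, 56 had exons overlapping another gene on either strand, 32 had a near-identical copy and 71 had at least one of these, so that their reads could have been divided between genes. On the same strand 15 had such an overlap, and overlaps on the other strand share reads only if the counting ignored strand.

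The tests were tested on simulated data drawn from the means and depths of these libraries, with known changes in 67, 67 and 66 genes. Over 10471 genes of the simulated comparison of aged with young cells, limma recovered 52.24% of the 1.5-fold, 83.58% of the 2-fold and 95.45% of the 4-fold changes, and called 15 unchanged genes. A simulated list of 20 genes shifted 1.5-fold reached an adjusted p of 2.76e-48 with the preset correlation and 0.00423 with the estimated one in camera, and 0 of 50 unchanged lists were called in either. The simulated genes vary independently, which real genes do not. In the 9 groupings of the real libraries that are not by age camera called 8 to 19 lists at the preset correlation, where limma called 0 genes. Each of these groupings mixes young and aged libraries on each side. Part of the age difference therefore stays in the contrast, and the rest adds to the spread within sides. These numbers are thus not rates of false calls for camera or limma.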

Results

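CD8 T cells, the lymphocytes that kill infected or malignant cells, were compared between mice aged 6 weeks (young) and around 65 weeks (aged) after activation in culture. The cells were isolated magnetically from the spleen, stimulated for 2 days on plates coated with antibodies to the T cell receptor (3 µg/ml) and to the costimulatory receptor CD28 (1 µg/ml) with interleukin 2 at 10 ng/ml, and then kept in interleukin 2 for 5 more days. RNA was collected after 7 days in total. There were 3 libraries per age group, called biological replicates in the labels, which do not say whether each came from its own mouse. The p-values below therefore measure the spread between these libraries. Any difference in culture between the age groups would also be part of the differences below, and the design does not separate it from age. Between 11371 and 11874 genes had at least 1 read in a library.

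The libraries separated by age. On log2(CPM + 1), the first principal component held 50.4% of the variance, with the young libraries at -29.9 to -25.3 and the aged libraries at 24.4 to 30.1, and the second component held 14.2%. On the second the aged libraries lay apart from each other, at 24.8, 2.90 and -25.8 for Aged replicates 1, 2 and 3, and the young libraries at -2.996 to 1.062. Across genes, pairs of libraries correlated at r = 0.974 to 0.98 within a group and 0.951 to 0.957 between groups, as a description over genes that are not independent.

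The comparison asked how the transcriptome of activated CD8 T cells differs with the age of the mouse. Of 17 tested genes of naive and memory T cells 15 fell in aged cells, and of 42 tested S phase genes 37 rose (camera adjusted p = 3.31e-15 and 7.36e-22, and adjusted p = 0.0625 and 0.102 with an estimated correlation). S1pr1, the receptor that guides T cells out of lymphoid tissue, was 44.4 ± 7.24 CPM in young and 2.19 ± 0.971 CPM in aged cells (SD, n = 3 per group), 20.3-fold lower. The size of this fold is uncertain, since the aged values of 1.15 to 3.07 CPM lie near the floor of a library. Gzmf, a granule protease of killer cells, was 49.6 ± 4.82 CPM in young and 389 ± 89.4 CPM in aged cells, 7.84-fold higher. Its 3' end is near-identical to that of Gzme, and Gzmd, Gzme, Gzmf, Gzmg and Gzmn summed were 2.82-fold higher. Of 10511 genes tested, limma called 1701 higher and 1313 lower in aged cells, and of these 195 were at least 2-fold higher and 392 at least 2-fold lower on the log2(CPM + 1) scale. With a pseudocount of 5 these were 60 and 156, and with a mean of at least 5 CPM 252 were at least 2-fold lower. The median log2 fold change of all tested genes was 0.03. The balance of higher and lower calls turned with RLE (1451 and 1532), upper-quartile (1465 and 1497) and TMM scaling (1432 and 1549), and with limma-voom (1436 and 1520), edgeR (1464 and 1578) and DESeq2 (952 and 1017). In 4296 genes (40.9%) the 2 groups did not overlap, where chance gives 10%.

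**Figure D1:**
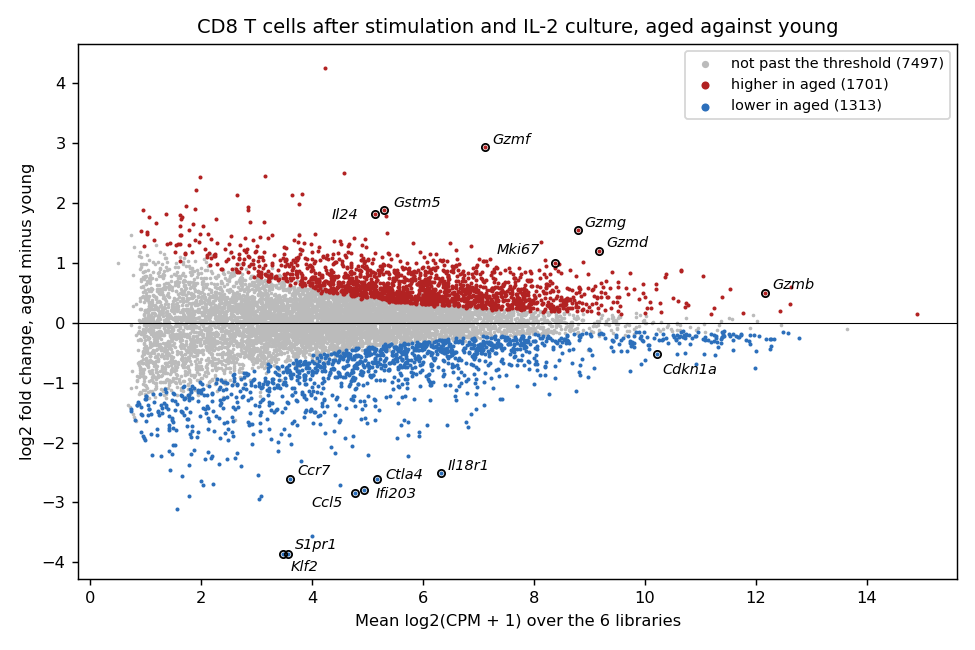
Each point is one gene, with its mean log2(CPM + 1) over the 6 libraries on the x axis and its log2 fold change, aged minus young, on the y axis. Genes past the threshold of limma are red (1701 higher in aged cells) or blue (1313 lower; 1432 and 1549 with TMM scaling), and Gzmf at 2.93 and S1pr1 at -3.87 lie far from 0 in their range of mean level.

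Among the 12 most reduced genes by the naming rule, S1pr1 (ENSMUSG00000045092, chromosome 3, 115710433 to 115715072, GRCm38) fell by 3.87 ± 0.26 (SE) on the log2 scale, with a limma adjusted p of 7.21e-09. Klf2 (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656), a transcription factor of quiescent T cells that drives S1pr1, was 43.0 ± 14.3 CPM in young and 1.94 ± 0.409 CPM in aged cells, 22.2-fold lower. The aged values of Klf2, like those of S1pr1, lie near the floor of a library, so the size of its fold is uncertain. Ccr7, a chemokine receptor for entry into lymph nodes, was 6.53-fold lower, at 29.0 ± 2.57 and 4.44 ± 2.53 CPM. Ctla4 (ENSMUSG00000026011, chromosome 1, 60887000 to 60915832), an inhibitory receptor, was 6.40-fold lower, at 87.9 ± 15.6 and 13.7 ± 3.21 CPM. Il18r1, a subunit of the interleukin 18 receptor, was 5.48-fold lower, from 189 ± 11.8 CPM in young cells, and the chemokine Ccl5 6.95-fold lower. The other genes of this group were Nrn1 (13.2-fold), Tgm2 (10.8-fold), Pygl (10.0-fold), Setbp1 (8.06-fold), Ifi203 (7.26-fold) and Napsa (7.12-fold). The aged means of Pygl, Tgm2 and Setbp1 were 2.22, 2.11 and 2.38 CPM, so the sizes of their folds are uncertain. Ifi203 has exons that overlap another gene's on the same strand, which leaves its value uncertain. Those of Nrn1, Tgm2 and Napsa overlap on the other strand, which leaves their values uncertain if the counting ignored strand.

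The 12 most increased genes were led in size by Gstp2, which was at 0 and 0.718 CPM in Young replicates 1 and 2 and at 46.1 CPM in Young replicate 3, against 64.0 to 91.3 CPM in aged libraries. It shares its 3' end with Gstp1, and its log2 fold change of 4.24 in limma was not called by DESeq2 (2.36, adjusted p = 0.492) or by edgeR's quasi-likelihood test (2.33, adjusted p = 0.219), so its change is uncertain. Gzmf (ENSMUSG00000015441, chromosome 14, 56205263 to 56211417) rose by 2.93 ± 0.12 (SE) on the log2 scale, with a limma adjusted p of 9.76e-12. Il24, a cytokine of the interleukin 10 family, was 3.64-fold higher, at 17.8 ± 4.06 and 65.0 ± 11.1 CPM, and Gstm5, a glutathione transferase, 3.77-fold higher, at 19.7 ± 3.90 and 74.4 ± 9.08 CPM. Klra7, an inhibitory receptor of the Ly49 family, was 4.08-fold higher, at 6.46 ± 3.56 and 26.4 ± 4.99 CPM. Cyp11a1, which starts steroid synthesis, was 5.56-fold higher with values of 14.6 to 47.5 CPM in the aged libraries. Fgfr1op was 3.68-fold, Cnbd2 3.58-fold, Exosc6 4.15-fold, Echdc1 3.91-fold and Gzmg 2.93-fold higher. Cyp11a1 and Exosc6 have exons that overlap another gene's on the same strand. Gzmf, Gzmg, Klra7, Cnbd2 and Exosc6 have a 3' end near-identical to another gene's. The values of all these genes are uncertain. Exons of Gzmf, Gstm5, Cnbd2 and Echdc1 overlap another gene's on the other strand, which adds uncertainty if the counting ignored strand. Echdc1 was at 0 in Young replicate 1 and 12.2 CPM in Young replicate 2, its log2 fold change of 2.45 was 1.495 without Young replicate 1, and DESeq2 (adjusted p = 0.392) and edgeR (adjusted p = 0.212) did not call it. Ly6c1 was 7.51-fold higher, at 9.27 ± 2.78 and 69.6 ± 56.9 CPM, and was not called by edgeR (adjusted p = 0.0885). Its 3' end is near-identical to that of Ly6c2, and the summed CPM of both was 994 ± 88.6 in young and 823 ± 126 in aged cells.

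Genes of naive and central memory T cells fell together. Of 17 tested members, 15 fell, 0 rose and 2 did not pass the test (16 fell when adjusted over the list alone), with a median log2 fold change of -1.24 (camera adjusted p = 3.31e-15 and adjusted p = 0.0625 with an estimated correlation). Besides S1pr1, Klf2 and Ccr7, they included the transcription factor Foxp1, at 267 ± 22.1 CPM in young and 113 ± 34.8 CPM in aged cells. Tcf7, which encodes the memory factor TCF-1, fell by 2.69 on the log2 scale, from 10.8 ± 1.93 to 1.04 ± 1.20 CPM. Il7r and Id3 had log2 fold changes of -0.37 and -0.56 that did not pass. In the list of chemokine receptors and integrins, 9 of 19 tested members fell and 0 rose (9 and 0 when adjusted over the list alone; camera adjusted p = 3.39e-08 and adjusted p = 0.0625 with an estimated correlation). Cxcr4 was 4.37-fold lower, at 53.1 ± 12.6 and 12.2 ± 3.47 CPM, and Ccr2 1.69-fold lower, at 706 ± 25.3 and 418 ± 34.9 CPM.

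**Figure D2:**
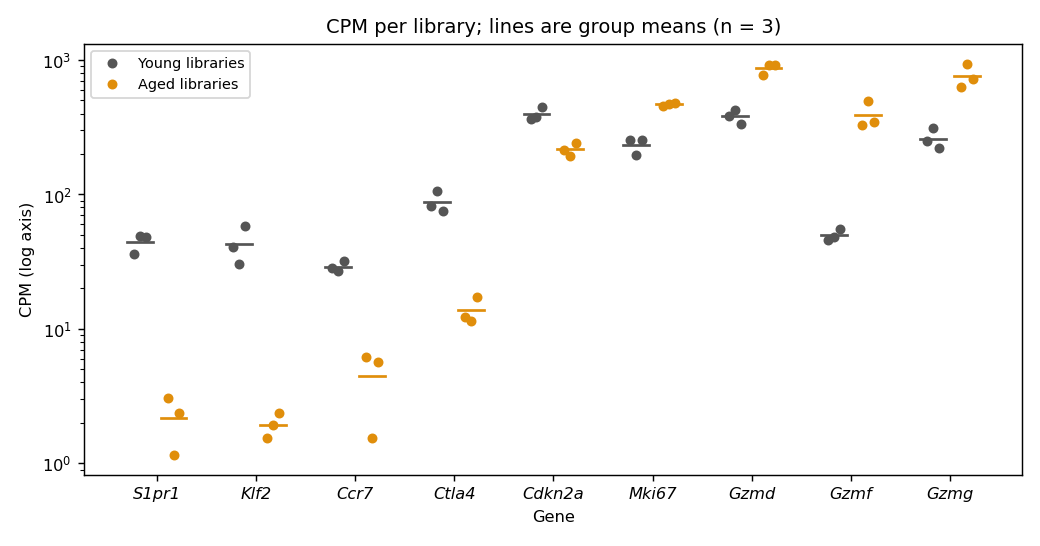
CPM per library (log axis) of genes of resting T cells, the inhibitory receptor Ctla4, the cell cycle genes Cdkn2a and Mki67, and granzymes; points are the 3 young and 3 aged libraries and lines are group means. In each gene shown the young and aged libraries do not overlap, and S1pr1 lies at 36.1 to 48.8 CPM in young against 1.15 to 3.07 CPM in aged libraries.

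The cytotoxic effector list moved in both directions. Of 19 tested members 7 rose, all of them granzymes, and 4 fell (7 and 4 when adjusted over the list alone). The risers were Gzmf, Gzmg (260 ± 46.2 to 761 ± 162 CPM), Gzmd (381 ± 46.1 to 875 ± 88.2 CPM), Gzmc (67.4 ± 9.92 to 141 ± 9.02 CPM), Gzme, Gzmb and Gzma. Gzmb, the main apoptosis-inducing granzyme, was 3865 ± 27.9 CPM in young and 5500 ± 695 CPM in aged cells, 1.42-fold higher. Gzmk fell 4.56-fold, from 20.1 ± 4.90 to 4.40 ± 1.62 CPM, and Serpinb6b, Ctsw and Nkg7 also fell. Perforin (Prf1) was 620 ± 41.8 and 643 ± 128 CPM and did not pass (limma adjusted p = 0.822; 95% interval of the log2 fold change -0.16 to 0.23). The list had a camera adjusted p of 0.048 for higher values (adjusted p = 0.19 with an estimated correlation), but a median of 0.04 that was -0.02, -0.01 and -0.01 with TMM, RLE and upper-quartile scaling, and the camera call was lost there (adjusted p = 0.0636, 0.0657 and 0.0604). It was also lost, with medians of -0.02 to 0.06, with limma-voom (0.0667), thinning (0.0544), a mean of at least 5 CPM (0.0924), a pseudocount of 0.1 (0.065), without genes with overlapping exons (0.0532), and without Young replicate 1 (0.0552), Young replicate 3 (0.0662) or Aged replicate 3 (0.0546). Gzmd, Gzme, Gzmf, Gzmg and Gzmn lie in a cluster on chromosome 14 and have near-identical 3' ends, so reads could be divided among them. Their summed CPM was 787 ± 102 in young and 2222 ± 326 in aged cells, 2.82-fold higher.

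Receptors shared with natural killer cells went both ways, with 7 of 14 tested members higher and 2 lower (8 and 3 when adjusted over the list alone), and the list was not called (camera adjusted p = 0.155), except with no filter on low values (0.0341). Klra1 was 8.15-fold higher, at 0.871 ± 0.789 and 7.10 ± 0.935 CPM, and Klrc1, which encodes the inhibitory receptor NKG2A, 1.45-fold higher, at 81.0 ± 0.139 and 118 ± 3.02 CPM. The young values of Klra1 lie near the floor of a library, so the size of its fold is uncertain. The 3' end of Klrc1 is near-identical to that of Klrc2, so reads could be divided between them. Klrk1, which encodes the activating receptor NKG2D, was 1.85-fold lower, at 64.7 ± 4.65 and 35.0 ± 3.30 CPM. Of 13 tested inhibitory receptors and exhaustion genes, 4 fell and 1 rose (5 and 2 when adjusted over the list alone; camera adjusted p = 0.0839). Camera called this list lower with no filter (0.039), with DESeq2 (0.0495) and with edgeR (0.0309). Cd160 was 1.75-fold lower, Cd101 was 2.76-fold lower and Lag3 fell by 1.38 on the log2 scale, while Lilrb4a was 1.83-fold higher. Exons of Lilrb4a overlap another gene's on the same strand, and its 3' end is near-identical to those of Gm49339 and Lilr4b. Its value is therefore uncertain. Cd101 lost its call without any one of Young replicates 1 and 2 and Aged replicates 2 and 3, with log2 fold changes of -1.09, -1.14, -1.06 and -1.02, and with DESeq2 and thinning. Pdcd1, which encodes PD-1, was 11.1 ± 2.13 and 10.6 ± 2.68 CPM and did not pass (limma adjusted p = 0.870). The list of age-associated CD8 T cells, marked in mice by Gzmk, Ccl5 and PD-1, had 4 of 12 tested members lower and 1 higher (4 and 1 when adjusted over the list alone; median -0.37; camera adjusted p = 0.0179 and adjusted p = 0.149 with an estimated correlation). Its call was lost without Young replicate 2 (median -0.18, camera adjusted p = 0.0512) and with DESeq2 (-0.45, 0.0616). Ccl5 and Gzmk are above, Cxcr6 was 2.06-fold lower, and Eomes rose by 0.35 on the log2 scale, which did not pass without Young replicate 3 (0.27) or without Aged replicate 3 (0.23), nor with DESeq2 (0.31). The virtual memory list had 5 of 14 members lower and 3 higher and was not called (camera adjusted p = 0.135).

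Cytokine genes were mixed, with 10 of 19 tested members higher and 3 lower (10 and 3 when adjusted over the list alone; camera adjusted p = 0.116). Without Aged replicate 3 the list was called higher, with a median log2 fold change of 0.41 against 0.63 over all libraries (adjusted p = 0.0332). Spp1, which encodes osteopontin, was 2.54-fold higher, at 177 ± 31.0 and 451 ± 87.5 CPM. Ltb, the lymphotoxin beta gene, was 3.56-fold lower, at 114 ± 11.2 and 31.8 ± 7.09 CPM, and Tnfsf8, the CD30 ligand, 2.39-fold lower. Ifng was at 1.93 ± 1.73 and 3.19 ± 1.32 CPM and did not pass. The type 2 cytokine list had 4 of 10 members higher and 2 lower (camera adjusted p = 0.266), and of the chemokines Ccl5 and Ccl4 were measurable, Ccl4 at 4.78 ± 1.32 and 4.01 ± 1.03 CPM.

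Genes of the cell cycle were higher in aged cells. Of 42 tested S phase genes 37 rose and 0 fell (41 and 0 when adjusted over the list alone), with a median of 0.84 (camera adjusted p = 7.36e-22 and adjusted p = 0.102 with an estimated correlation). Mcm7 and Mcm3, subunits of the replicative helicase, were 2.06-fold and 1.87-fold higher, and Nasp and Hells, which act on chromatin, 2.05-fold and 1.96-fold. In the G2 and M phase list 43 of 47 rose and Psrc1 fell (43 and 1 when adjusted over the list alone; median 0.74; camera adjusted p = 3.23e-19 and adjusted p = 0.181 with an estimated correlation). The proliferation marker Mki67 was 235 ± 33.3 CPM in young and 468 ± 12.8 CPM in aged cells, and Cdk1, the kinase that starts mitosis, 94.0 ± 16.2 and 192 ± 20.4 CPM. Cenpe and Birc5 were 1.83-fold and 1.78-fold higher. The list of core histones, which also holds linker histones such as Hist1h1b, had 12 of 29 members higher and 0 lower (12 and 0 when adjusted over the list alone; camera adjusted p = 5.3e-05 and adjusted p = 0.181 with an estimated correlation). Poly(A) transcripts of histone genes are a minor form. Hist1h1b was 1.98-fold higher.

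In the list of p53 targets and cell cycle inhibitors 14 of 30 tested members fell and 2 rose (14 and 2 when adjusted over the list alone; median -0.43; camera adjusted p = 2.95e-06 and adjusted p = 0.0625 with an estimated correlation). Of the members 14 did not pass, Cdkn2d among them (log2 fold change -0.12). Cdkn2a, the locus of the senescence markers p16 and p19ARF, was 395 ± 43.8 CPM in young and 217 ± 24.2 CPM in aged cells, 1.82-fold lower, and Cdkn1a, which encodes p21, 1424 ± 32.7 and 995 ± 37.5 CPM, 1.43-fold lower. Cdkn1b, which encodes p27, was 2.09-fold lower, and Trp53inp1 3.39-fold lower, at 205 ± 16.5 and 60.5 ± 5.01 CPM. The 2 that rose were Cdkn2c and Gadd45g. Among apoptosis regulators 5 of 26 fell and 1 rose (5 and 1 when adjusted over the list alone; camera adjusted p = 0.0379 and adjusted p = 0.156 with an estimated correlation). The pro-apoptotic genes Bcl2l11, which encodes BIM, and Bbc3, which encodes PUMA, were 2.47-fold and 3.18-fold lower, the death receptor Fas 7.59-fold lower at 8.96 ± 0.914 and 1.18 ± 0.614 CPM, and Cycs, the cytochrome c gene, 1.57-fold higher. The aged values of Fas lie near the floor of a library, so the size of its fold is uncertain. The list of apoptosis regulators had a median of -0.23 and lost its camera call without Young replicate 1 (median -0.20, adjusted p = 0.0517), without Young replicate 3 (-0.16, 0.106) and without genes with overlapping exons (-0.24, 0.0532). The secretory phenotype of senescence had 3 of 11 members lower and 2 higher and was not called (camera adjusted p = 0.116).

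**Figure D3:**
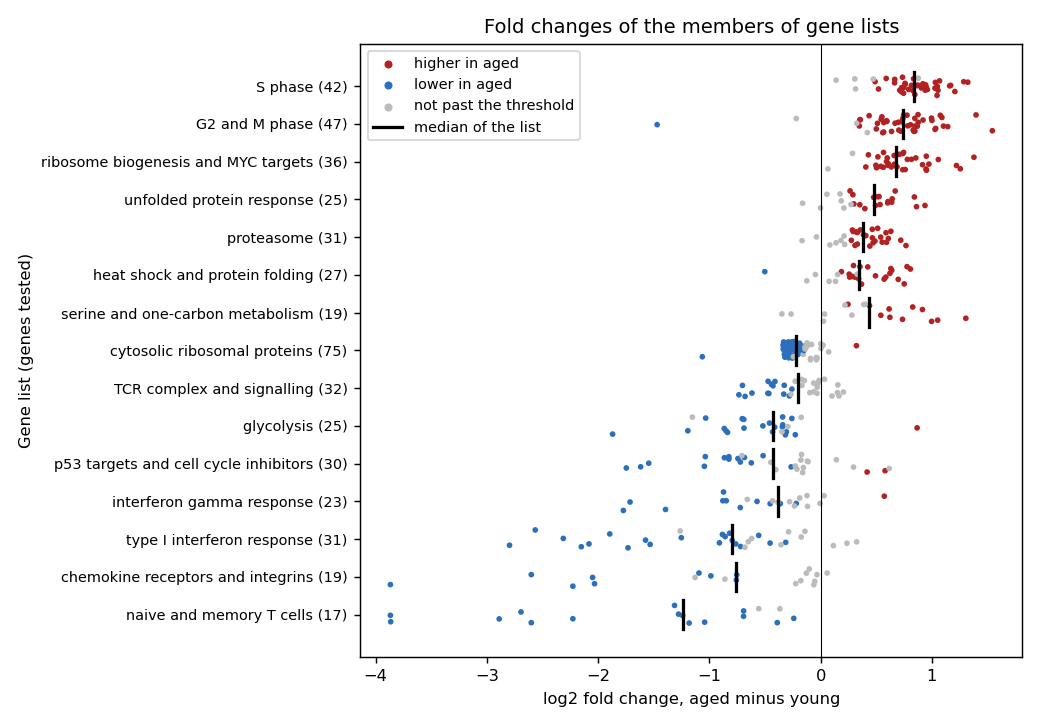
Log2 fold change, aged minus young (x axis), of the tested members of selected gene lists (y axis, with the number of genes tested). The lists were fixed beforehand, but those shown are a part of the lists that camera called at the preset correlation. Lists that were not called are not drawn. Each point is a gene, red or blue where limma called it higher or lower in aged cells and grey otherwise, and the black line is the list's median. S phase genes have a median of 0.84 and naive and memory genes one of -1.24.

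Lists of protein production and folding moved in both directions. Of 36 ribosome biogenesis genes and MYC targets 34 rose and 0 fell (35 and 0 when adjusted over the list alone; median 0.68; camera adjusted p = 2.31e-21 and adjusted p = 0.0625 with an estimated correlation). Srm and Odc1, enzymes of polyamine synthesis, were 2.35-fold and 1.90-fold higher, and the nucleolar genes Nolc1 and Nop56 2.10-fold and 1.94-fold. Of 75 cytosolic ribosomal protein genes 56 fell and 1 rose (62 and 1 when adjusted over the list alone; median -0.22; camera adjusted p = 6.6e-20 and adjusted p = 0.172 with an estimated correlation), and Rplp0 was 2979 ± 95.4 CPM in young and 2367 ± 79.6 CPM in aged cells. Heat shock and folding genes rose in 20 of 27 and fell in 1 (20 and 1 when adjusted over the list alone; median 0.34; camera adjusted p = 1.87e-10 and adjusted p = 0.12 with an estimated correlation). Hsp90aa1, an HSP90 chaperone, was 1612 ± 130 and 2758 ± 108 CPM, 1.71-fold higher, and the mitochondrial chaperonin Hspd1 was 1.75-fold higher. In the unfolded protein response list 18 of 25 rose and 0 fell (19 and 0 when adjusted over the list alone; median 0.48; camera adjusted p = 1.87e-10 and adjusted p = 0.12 with an estimated correlation), among them Hspa5, the chaperone BiP of the endoplasmic reticulum, at 944 ± 35.8 and 1471 ± 19.7 CPM. Proteasome subunits rose in 24 of 31 and fell in 0 (26 and 1 when adjusted over the list alone; median 0.39; camera adjusted p = 3.96e-11 and adjusted p = 0.134 with an estimated correlation), with Psmd1 1.70-fold higher.

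Metabolic lists moved apart. Glycolysis genes fell in 20 of 25 and rose in 1 (22 and 1 when adjusted over the list alone; median -0.43; camera adjusted p = 5.95e-13 and adjusted p = 0.12 with an estimated correlation). Aldoc was 3.78-fold lower, at 102 ± 17.3 and 26.9 ± 2.49 CPM, the glucose transporter Slc2a3 2.28-fold lower, at 187 ± 3.76 and 82.1 ± 14.4 CPM, Gpi1 1.83-fold and Aldoa 1.62-fold lower. The riser was the lactate transporter Slc16a1. Genes encoded in mitochondrial DNA fell in 8 of 13 and rose in 0 (9 and 1 when adjusted over the list alone; median -0.23; camera adjusted p = 1.81e-05 and adjusted p = 0.172 with an estimated correlation), and mt-Co1 was 2950 ± 232 and 2038 ± 72.7 CPM. The camera call was lost without genes with overlapping exons (median -0.35, adjusted p = 0.0807). Mitochondrial genes took 3.13 ± 0.215% of CPM in young and 2.60 ± 0.0889% in aged libraries. Nuclear genes of the respiratory chain rose in 14 of 74 and fell in 8, and the list was not called (camera adjusted p = 0.764). Tricarboxylic acid cycle genes rose in 9 of 25 and fell in 1 (10 and 1 when adjusted over the list alone; camera adjusted p = 0.022 and adjusted p = 0.149 with an estimated correlation), and the call was lost with DESeq2 (median 0.22 against 0.23, 0.0582) and edgeR (0.20, 0.0546). Serine and one-carbon metabolism rose in 11 of 19 and fell in 0 (12 and 0 when adjusted over the list alone; median 0.44; camera adjusted p = 7.93e-06 and adjusted p = 0.0625 with an estimated correlation), with Mat2a 1.89-fold and Mthfd2 1.54-fold higher. Glutamine and aspartate metabolism rose in 9 of 19 and fell in 1 (10 and 2 when adjusted over the list alone; camera adjusted p = 0.000785 and adjusted p = 0.17 with an estimated correlation), with Cad, which starts pyrimidine synthesis, 2.24-fold higher, at 40.8 ± 12.004 and 91.2 ± 7.11 CPM. Cholesterol synthesis rose in 8 of 24 and fell in 0 (9 and 0 when adjusted over the list alone; camera adjusted p = 0.00811 and adjusted p = 0.216 with an estimated correlation). Its camera call was lost without genes with overlapping exons (median 0.15 against 0.19, 0.072). Autophagy and lysosome genes fell in 11 of 39 and rose in 1 (11 and 1 when adjusted over the list alone; camera adjusted p = 0.00811 and adjusted p = 0.156 with an estimated correlation), among them Npc2 and Sqstm1, 1.38-fold and 1.36-fold lower.

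Interferon-induced genes were lower in aged cells. Of 31 tested genes of the type I interferon response 20 fell and 0 rose (22 and 0 when adjusted over the list alone; median -0.79; camera adjusted p = 2.14e-11 and adjusted p = 0.0625 with an estimated correlation). Ifi209 was 117 ± 17.9 CPM in young and 30.7 ± 5.67 CPM in aged cells, and Ifi208 was 4.55-fold lower. Isg15 and Mx1 had log2 fold changes of -0.36 and -0.17 that did not pass. In the interferon gamma response 12 of 23 fell and 1 rose (13 and 1 when adjusted over the list alone; median -0.38; camera adjusted p = 1.05e-06 and adjusted p = 0.122 with an estimated correlation). The GTPase gene Gbp2 was 87.0 ± 7.25 and 26.0 ± 4.55 CPM, 3.34-fold lower, Iigp1 was 2.62-fold lower, and the riser was Socs1, an inhibitor of cytokine signalling. The camera call of this list was lost without genes with overlapping exons (median -0.66, adjusted p = 0.0532).

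T cell receptor complex and signalling genes fell in 14 of 32 and rose in 0 (15 and 0 when adjusted over the list alone; median -0.20; camera adjusted p = 4.09e-05 and adjusted p = 0.0625 with an estimated correlation). Cd3d was 773 ± 34.7 and 581 ± 14.4 CPM, 1.33-fold lower, Cd3g 1.39-fold and Themis 1.64-fold lower. Costimulatory receptors fell in 4 of 15 and rose in 0 (4 and 0 when adjusted over the list alone; camera adjusted p = 0.00456 and adjusted p = 0.12 with an estimated correlation), with Cd27 2.58-fold lower and Slamf6 at 8.42 ± 1.12 CPM in young cells and 0 to 1.02 CPM in the aged libraries. This list's camera call was lost without genes with overlapping exons (median -0.17 against -0.19, adjusted p = 0.0532). Effector transcription factors fell in 6 of 15 and rose in 2 (6 and 2 when adjusted over the list alone; median -0.21; camera adjusted p = 0.0076 and adjusted p = 0.122 with an estimated correlation). Prdm1, which encodes BLIMP-1, was 2.06-fold lower, Rora 3.85-fold and Runx3 1.36-fold lower, and Irf8 was 1.78-fold higher, at 90.9 ± 12.9 and 162 ± 1.66 CPM. Without Young replicate 3 this median was -0.32 and without Aged replicate 2 it was -0.12, with the call kept in both. Without genes with overlapping exons it was -0.12 and the camera call was lost (adjusted p = 0.256). Interleukin 2 and STAT5 signalling had 9 of 26 lower and 4 higher (11 and 4 when adjusted over the list alone; camera adjusted p = 0.024 and adjusted p = 0.156 with an estimated correlation), with Lta 2.34-fold lower and Cish 1.36-fold higher. Its camera call was lost without genes with overlapping exons (median -0.09 against -0.11, 0.25) and without Aged replicate 3 (-0.10, 0.0546). Immediate early and AP-1 genes fell in 7 of 28 and rose in 2 (8 and 3 when adjusted over the list alone; camera adjusted p = 0.00811 and adjusted p = 0.149 with an estimated correlation), and those that fell included the antiproliferative genes Btg1 and Btg2, at 2.03-fold and 2.08-fold, and Nfkbia, at 2.03-fold. Of 4 tested type 17 genes Rora, Tmem176a and Tmem176b fell (3 when adjusted over the list alone; camera adjusted p = 0.00867 and adjusted p = 0.17 with an estimated correlation). The call was lost with no filter (median -0.16 against -1.49, camera adjusted p = 0.0621).

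CD8 mRNA was present throughout and Cd4 was near 0. Cd8a was 270 ± 5.69 CPM in young and 303 ± 52.2 CPM in aged cells (limma adjusted p = 0.259; called higher without Aged replicate 3, with a log2 fold change of 0.30 against 0.15), Cd8b1 383 ± 21.7 and 304 ± 27.2 CPM (limma adjusted p = 0.00209), and Cd3e 226 ± 4.32 and 168 ± 11.4 CPM. The 3' end of Cd8b1 has near-identical matches in 8 other genes, so its value is uncertain. Cd4 was at most 0.384 CPM in any library. MHC class II and dendritic cell markers fell in 5 of 10 and rose in 0 (5 and 0 when adjusted over the list alone; camera adjusted p = 0.0185 and adjusted p = 0.172 with an estimated correlation), with H2-Ab1 at 55.5 ± 1.496 and 16.8 ± 1.48 CPM, while Cd74, H2-Aa and H2-Eb1 were at most 1.54 CPM in any library. The camera call was lost without genes with overlapping exons, with a median of -0.52 in both (adjusted p = 0.0575). Of the same list Xcr1 was 3.09-fold, H2-DMa 3.15-fold and H2-DMb2 3.33-fold lower, and H2-DMb2 lost its call without Young replicate 1 (log2 fold change -1.08), without Young replicate 3 (-1.11) and without Aged replicate 3 (-0.93), and with DESeq2 and limma-voom. The macrophage and monocyte list had 2 of 6 tested members lower, Ccr2 and Cd68, and 0 higher (3 and 0 when adjusted over the list alone; median -0.55; camera adjusted p = 0.048 and adjusted p = 0.172 with an estimated correlation). Ccr2 is also a receptor of activated T cells. The call was lost with each of the 6 libraries left out, with medians of -0.57 to -0.20, and with TMM, RLE and upper-quartile scaling, no filter, limma-voom, thinning and the replicate block, with medians of -0.65 to -0.15. Cd68, at 14.3 ± 2.93 and 8.28 ± 2.61 CPM, lost its call without Young replicate 1, Young replicate 2, Aged replicate 1 or Aged replicate 2. Cd79b, a B cell receptor component, was 6.34 ± 3.74 and 0.982 ± 0.852 CPM, but Cd79a and Ms4a1 were at 0 in every library, and the B cell list was not called (1 of 3 lower; camera adjusted p = 0.0913). Hbb-bt, a globin gene, was 7.97 ± 2.99 CPM in young cells and had 0 reads in aged cells, at least 17.8-fold lower against 3 reads over the group. The erythroid list (1 of 5 lower and 1 higher, camera adjusted p = 0.218), CD4 T cell markers (2 of 5 lower and 1 higher, camera adjusted p = 0.332), natural killer and innate lymphoid markers (1 of 6 lower and 2 higher, camera adjusted p = 0.533) and stromal markers (1 of 3 higher, camera adjusted p = 0.975) were not called. The stromal riser was Thy1, which T cells also express, at 968 ± 16.3 and 1150 ± 74.9 CPM. The CD4 list had a median of 0.09 with a test direction towards lower values. Ly6g was 94.6 ± 10.5 and 89.7 ± 36.9 CPM with S100a8 at 0 in every library. The basophil gene Mcpt8 was 6.65 ± 0.268 and 11.3 ± 4.97 CPM and did not pass (limma adjusted p = 0.122). Cpa3, the other of the 2 tested mast cell and basophil markers, fell from 7.39 ± 2.83 to 1.75 ± 1.515 CPM and passed. Ly6g passed the test as lower without Aged replicate 2 (log2 fold change -0.45). Neutrophil, mast cell and gamma delta T cell lists had fewer than 3 tested genes.

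The remaining lists were not called by camera. MHC class I presentation had 5 of 16 members lower and 3 higher (adjusted p = 0.0839), the ATF4 and amino acid stress response 12 of 31 higher and 7 lower (0.139), antioxidant and glutathione genes 9 of 26 higher and 4 lower (0.135), fatty acid synthesis 5 of 15 higher (0.135) and fatty acid oxidation 3 of 20 lower and 1 higher (0.135). TGF-beta and tissue residency genes had 2 of 16 lower and 1 higher (0.341), and menin, Polycomb and DNA methylation factors 5 of 31 higher and 4 lower (0.933), with a median of -0.02 and a test direction towards higher values. In that last list Dnmt1 and Ezh2 rose by 0.67 and 0.48 on the log2 scale, Tet1 fell by 1.40, and Men1 had a log2 fold change of -0.02 that did not pass.

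In total camera called 12 lists higher and 19 lower at the preset correlation and 0 with an estimated one, and fry called 42 of the 50 tested lists, these 31 among them.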

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

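Of 3539 values of named genes and gene lists under the alternatives, 3428 kept their direction and their side of the threshold, 103 were weaker, 31 of them list calls with the estimated correlation, 7 were stronger and 1 reversed. The reversed one was Ly6g, with a log2 fold change of 0.1524 without Aged replicate 3, and the cause was not tested. Without Aged replicate 2 it was -0.4511 and passed the test. With a mean of at least 5 CPM, 252 genes were at least 2-fold lower, and with a pseudocount of 5, 60 were at least 2-fold higher and 156 lower, since that pseudocount shrinks the log2 fold changes of genes at low levels. DESeq2 called 952 genes higher and 1017 lower, 1969 in all against 3014 with limma and 3042 with edgeR, and the cause was not tested. On the simulated data DESeq2 also recovered fewer changes and called fewer unchanged genes than limma and edgeR. Without genes with overlapping exons, 6462 genes were tested, fewer by construction, with 1091 higher, 862 lower, 128 at least 2-fold higher and 12 lists lower. With an estimated correlation 0 lists were higher and 0 lower. The runs with edgeR, TMM-scaled CPM and without overlapping genes were chosen after seeing the data. With TMM, RLE and upper-quartile scaling 48 to 49.5% of called genes were higher, against 56.4%.

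Leaving out each replicate in turn gave 1322 to 1582 genes higher and 1011 to 1207 lower, 145 to 249 at least 2-fold higher and 323 to 411 at least 2-fold lower, and 11 to 13 lists higher and 17 to 19 lower. The replicate number as a block gave 1725 genes higher and 1336 lower, 2955 of them shared with the fit without it, and 12 lists higher and 18 lower. The macrophage and monocyte list was not called there (camera adjusted p = 0.0531), and the block changed no other call of a named gene or list. Libraries with the same number deviated from their group means with correlations of 0.00025 to 0.0209, against -0.0259 to 0.0242 over all pairs across groups. These correlations were near 0. The range over all pairs includes the same-number pairs, so it does not decide whether the numbers paired the samples. Depth limits the genes at low levels, where 1 read was 0.359 to 0.512 CPM.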

Other observations

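The gene groups of this paragraph were chosen after their values were seen. Counts are given for families of neighbouring genes, with no test of the families. Of 9 tested genes of the interferon-inducible p200 cluster on chromosome 1 (173350879 to 174031810, GRCm38) 8 fell, with a median log2 fold change of -1.92, and Mndal was 151 ± 16.96 CPM in young and 61.5 ± 11.9 CPM in aged cells (SD, n = 3 per group). The near-identical Ifi208 and Ifi213 together were 4.79-fold lower in aged cells. Of 8 Gimap genes, GTPases of lymphocyte survival, 6 fell (median -0.45), Gimap6 from 97.1 ± 7.31 to 48.6 ± 3.82 CPM. Of 5 tested Ms4a genes 3 fell and 1 rose, and Ms4a4b, a membrane protein of T cells, was 469 ± 20.7 and 204 ± 14.01 CPM. Tnfrsf22, Tnfrsf23 and Tnfrsf26, neighbouring genes of the tumour necrosis factor receptor family, all fell, Tnfrsf26 from 34.8 ± 6.83 to 9.28 ± 3.57 CPM. Of 6 tested Slfn genes 3 fell and 1 rose, with log2 fold changes of -1.73 to 0.54. Of 5 tested Klra genes 4 rose, and the CPM summed over the 11 listed genes was 15.2 ± 6.10 in young and 55.7 ± 3.83 in aged cells.

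The values of 5 genes per aged library, chosen after they were seen and without a test between these libraries, were as follows. Il13 was 13.8, 29.1 and 4.71 CPM in Aged replicates 1, 2 and 3, Il5 was 4.61, 13.0 and 0.941 CPM, Il10 was 46.1, 59.4 and 24.9 CPM, Il24 was 64.5, 76.3 and 54.1 CPM, and Ecm1, a matrix protein gene outside the type 2 list, was 24.6, 50.2 and 13.7 CPM. In the young libraries Il13 was 1.74 to 3.84 CPM, Il5 0.435 to 1.15 CPM and Il10 20.75 to 21.7 CPM. Il24 was 14.35 to 22.3 CPM there and Ecm1 10.05 to 13.1 CPM. Il5 in Aged replicate 3 thus lay inside the young range.

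Among the 10 ways to split the 6 libraries into 3 and 3, 1 split, the one by age, gave 3014 genes past the limma threshold, and the highest other gave 0. For gene lists the split by age gave 31, and the others 8 to 19, the highest other being 19, so again 1 split reached the real number. With 10 splits the share is never under 0.1, so they are too few for a share under 0.05. Every split other than that by age also mixes young and aged libraries on each side. Part of the age difference then stays in the contrast, and the rest adds to the spread within sides. The other splits therefore do not show how many genes or lists would be called without an age difference.

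The lower glycolysis genes of aged cells were weighed against 3 technical explanations, and the tests of scaling and of oxygen were chosen once the fall was known. Under TMM, RLE and upper-quartile scaling the list's median nearest 0 was -0.476, and the 16 of 25 members without a near-identical copy had a median of -0.436, which speaks against scaling and shared reads as the whole cause. The hypothesis that young cultures had less oxygen or were denser at harvest predicts a fall of other hypoxia-induced genes. Of 29 tested genes of that kind outside the list 18 fell and 1 rose, with a median of -0.744, Egln3 from 261 ± 28.8 to 111 ± 34.9 CPM and Vegfa from 31.6 ± 4.12 to 15.4 ± 3.31 CPM. That result is what a difference in culture would give, but a difference in the cells with age could give it too, and these data do not separate the 2. A difference in culture was not tested for the other lists, those of the cell cycle and of naive and memory T cells among them.

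There were 18 genes at or under 1 CPM in 1 replicate and at or over 10 CPM in another of the same group, 0.171% of tested genes, and 3 of them passed the threshold: Gstp2, Echdc1 and Il5. All 18 (100%) had overlapping exons on either strand or a near-identical copy, against 141 of 342 (41.2%) other genes of the same mean level (Fisher's exact test, two-sided, p = 2.32e-07). With same-strand overlaps or copies only, these were 12 of 18 (66.7%) and 45 of 342 (13.2%) (Fisher's exact test, two-sided, p = 7.42e-07). That fits reads being divided between genes for part of the 18. Overlaps on the other strand share reads only if the counting ignored strand, which is not given. Il5 had overlapping exons and 0 near-identical copies. For Gstp2, in a test chosen after its values were seen, the summed Gstp1, Gstp2 and Gstp3 CPM had a log2 fold change of -0.218 against 4.24 for Gstp2 alone. Had Gstp2 alone changed, the sum would have moved by only 0.34, since Gstp1 makes up most of it. The aged sums would then have been 294 to 321 CPM. They were 193 to 231.5 CPM, which argues against a change of Gstp2 alone. Gstp1 and Gstp3 fell by 0.797 and 1.20 on the log2 scale. Reads divided between Gstp1 and Gstp2, or separate changes of these genes, could give the fall of Gstp1. This test therefore does not decide, and the cause of the Gstp2 values stays open. Gstp3 had 0 near-identical copies and no overlapping exons, so divided reads would not be expected to lower it. No biological explanation was tested for these genes.

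The fall of H2-Ab1 was weighed against antigen-presenting cells left in the young cultures and against scaling, in tests chosen after the fall was seen. Such cells bring Cd74, H2-Aa and H2-Eb1, whose highest value in any young library was 1.30 CPM, 2.35% of H2-Ab1 at 55.5 ± 1.496 CPM, which speaks against them. Under TMM, RLE and upper-quartile scaling the log2 fold change of H2-Ab1 nearest 0 was -1.71, which speaks against scaling. The change with age itself was the remaining difference named in the labels, and its cause was not tested. A difference in culture between the age groups was not tested for H2-Ab1 either, and these data do not separate it from age.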
